A study of Homo sapiens with 9 samples.

How the data were processed

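RNA was measured in 9 libraries of PC9 cells with the FUCCI4 reporter, sorted into G1, S and G2 at day 0 and after 28 days of 500 nM osimertinib. Per the labels' protocols the cells were fixed with glyoxal and permeabilised with saponin before sorting, poly(A) RNA was made into strand-specific libraries with 10 to 18 PCR cycles, and 75 bp single-end reads were sequenced to an average of 24 M (M for mega) per sample. The reads recovered from the file average 43.0 M over 1 span per gene, and the labels do not explain the difference. Each of the 9 value columns matched 1 sample by day, phase and clone.

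The deposited file holds log2 values for 80037 coding transcripts. Per the submitters' processing notes, reads were aligned to GRCh38 with HISAT2 2.1.0, and DESeq2 is named as a tool without a version. Neither the read counter nor the scaling is stated. Checked from the values, each library's entries step in whole multiples of 1 amount, so each is log2 of a whole number of reads times 1 factor per library, with 0.9 reads entered for none, and 100% of values up to 1000 reads fell within 0.05 of a whole number of reads. Of the 68500 transcripts named in GENCODE v29, 59788 (87.3%) had the coordinates of their coding span, from start to stop codon. In 0 of 1579995 comparisons of a span nested in another of the same gene did the inner span hold more reads, so introns are counted. Genes inside a gene of the same strand held more reads than their host in 0 of 120 cases, and those on the opposite strand in 54 of 137 (day 0 G1 clone 1, at least 50 reads), so strands are kept apart. The values therefore mix unspliced and spliced RNA, and reads outside the coding span are missing.

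Each gene was represented by its coding span with the highest mean log2 value, the widest in 97.7% of genes. The 18 transcripts without a gene name took it from the transcript name, and 18 symbols carried 2 gene IDs. The log2 values were put back on the linear scale, 1 was added, and log2 was taken again. Folds are on that scale. Genes entered the tests with a mean log2 of at least 7.01, the value of 10 reads in the shallowest library, which left 12403 of 20435. Reads over these spans numbered 8.83 to 108.7 M per library, and 8.74% to 19.7% of transcripts had no read. A value of 10 reads in the shallowest library carries a wide counting error.

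Tests were run in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with trend, Benjamini-Hochberg adjusted p under 0.05), with the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The models, comparisons, gene lists and naming rule were fixed before the data were examined. Some single genes are not reported here. Day 28 against day 0 used day and phase as terms, clone 7 against clone 1 used clone, day and phase, and the day-by-phase term used 1 coefficient for S and G2 together. The comparisons within a day or a phase used 6 group means, with 1 spread pooled over the groups, so the 3 groups with 1 library were assumed to vary like the others. G2 at day 28 against day 0, with 1 library each, was described without a test. The planned count tests (edgeR and DESeq2) were not run on these log2 values, for which limma had been named in advance.

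Libraries of 1 clone share its label. The deviations of clone 7 from clone 1 correlated at 0.651 between day 0 G1 and day 0 S, 0.114 between day 0 G1 and day 28 G1, and 0.295 between day 0 S and day 28 G1. The planned fits without the clone are reported. The fit with the clone as a replicate block is given where it changed a call or moved a count by more than 1.5 times. It called 1938 genes for day 28 in S.

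The 38 gene lists were drawn up from general knowledge. The 33 lists with 5 or more tested genes were tested with camera (correlation 0.01) in 7 comparisons, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. The 5 lists with fewer were those of replication-dependent histones, MHC class II, APOBEC3, leukocyte markers and fibroblast and endothelial markers. Lists were not tested for day 28 in S nor for the clones.

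Genes were named by a rule. For day 28 against day 0 these were the 12 largest changes each way among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3, a symbol that is not of a pseudogene or clone, and 1 direction in each phase and each G1 clone pair. Each other tested comparison took the 4 largest each way with 1 direction over all pairs of libraries, each list up to 4 members with the largest change, and 15 genes were named whatever their result (EGFR, ERBB2, ERBB3, MET, AXL, DUSP6, SPRY4, CCND1, CDKN1A, CDKN1B, MKI67, CCNE2, CCNB1, CDT1 and GMNN). The text leaves out some list members.

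Alternatives fixed before the data were examined were a median-of-ratios scaling, no filter, a filter of 1 CPM in 4 libraries, pseudocounts of 0.1 and 5, the clone as a replicate block, clone 1 alone, the mean of the within-phase differences, the 4 G1 libraries alone, and each library left out in turn. Chosen after seeing the data were quantile scaling, voom on the recovered reads, a narrower span per gene (the narrowest within 2 log2 units of the highest), subtraction of the read density over 414 olfactory receptor genes (449.8 kb) times each span, and removal of each library's trends with span, coding length and GC content (splines, with coding length known for 99.2% and GC for 97.7% of tested genes), alone or with the clone block. Also chosen then was the division of 944 genes into the part of the coding span before a narrower coding span with the same end (at least 5 kb, at most 5% exonic) and the rest. The rest had to be more exonic than that part. The splits of the 9 libraries into other groups of the same sizes were chosen then too.

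The code was tested on simulated reads for 12403 genes, 200 of them changed. For day 28 against day 0 it recovered 83% of 2-fold and 100% of 4-fold changes, with 10 false among 193 calls, and in G1 34% and 100%, with 14 false among 148. The figures were 18% and 94% for day 28 in S, 20% and 99% for S and 22% and 89% for G2 against G1 at day 0, 10% and 88% for S and 5% and 86% for G2 against G1 at day 28, 7% and 71% for the day-by-phase term and 56% and 100% for the clones. A 2-fold change in most of these comparisons would therefore go unseen.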

Results

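The series asked what the transcriptome of PC9 cells looks like after 28 days of osimertinib in each phase of the cell cycle. PC9 is a human lung adenocarcinoma line that depends on a mutant epidermal growth factor receptor (EGFR), which osimertinib inhibits. The cells carried the FUCCI4 reporter, of which the labels name the fluorescent CDT1 and geminin (GMNN) markers, whose levels rise and fall with the cell cycle. Cells treated with 500 nM osimertinib for 28 days and untreated cells (day 0) were fixed, sorted into G1, S and G2 by DNA content and reporter colour, and profiled by strand-specific poly(A) RNA-seq. The 9 libraries came from 2 clones: at day 0 there were 2 G1 (clones 1 and 7), 2 S (clones 1 and 7) and 1 G2 library (clone 1), and at day 28 there were 2 G1 (clones 1 and 7), 1 S and 1 G2 library (clone 1). No label says if libraries of a clone were cultured apart. The p-values use spread between libraries and may count fractions of 1 culture as replicates.

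The libraries held between 8.83 M reads (day 0 G1 clone 7) and 108.7 M reads (day 0 G1 clone 1) over 1 span per gene, a 12.3-fold range around a mean of 43.0 M (M for mega). Why the labels give 24 M per sample is not known. The day 28 libraries were closer in depth, at 30.5 and 33.5 M reads in G1 (clones 1 and 7), 40.9 M in S and 43.1 M in G2. Transcripts of the mitochondrial genome took 6.07% to 10.7% of the reads at day 0 and 19.6% (G1 clone 1), 8.61% (G1 clone 7), 21.6% (S) and 15.8% (G2) at day 28. Genes whose coding span exceeded 300 kb took 0.726% to 1.05% of the reads at day 0 and 2.06% to 3.41% at day 28. Reads in 414 olfactory receptor genes, taken as a gauge of background, lay at 0.00108 to 0.00453 reads per kb per M reads at day 0. At day 28 they lay at 0.00769 to 0.0258. These densities rest on few reads, as few as 15 in day 0 S clone 7. They are also no floor. In day 28 G2 the 5th percentile of genes with spans over 300 kb was 0.0180, below the olfactory density of 0.0258. Subtracting that density can therefore take too much from long genes. The principal component with the most variance (60.6%) separated the days, with each day 0 library below and each day 28 library above 0. Each value counts reads over a coding span with introns, so it mixes spliced and unspliced RNA.

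The comparison of day 28 with day 0 over all phases asked what the surviving cells express. Osimertinib-treated cells gave far more reads over the coding span of GAB2, introns included, at 13.11 ± 0.53 (SD, n = 4) against 7.39 ± 1.26 (SD, n = 5) on the log2 scale. GAB2 is a docking protein of receptor tyrosine kinase signalling. The phase-adjusted log2 fold change was 5.56 ± 0.49 (SE), or 47.0-fold (adjusted p = 2.29e-05, ENSG00000033327, chromosome 11, 78219272 to 78417720). PSG5, a pregnancy-specific glycoprotein of the placenta, rose by 5.27 ± 0.62 (adjusted p = 9.03e-05, ENSG00000204941, chromosome 19, 43170095 to 43186405). SEMA5A, a semaphorin of axon guidance, rose by 5.12 ± 0.35 (adjusted p = 1.32e-05). The steepest fall was in TGM2, a transglutaminase that cross-links proteins, from 14.75 ± 0.42 (SD, n = 5) to 8.72 ± 1.45 (SD, n = 4). Its log2 fold change was -5.95 ± 0.47 (adjusted p = 1.85e-05, ENSG00000198959, chromosome 20, 38130219 to 38165198). AGR2, a disulfide isomerase needed for mucin folding, followed at -5.75 ± 0.73 (adjusted p = 1.43e-04, ENSG00000106541, chromosome 7, 16792908 to 16801796). VIM, the intermediate filament of mesenchymal cells, stood at -4.69 ± 0.57 (adjusted p = 1.08e-04, ENSG00000026025, chromosome 10, 17229423 to 17237271).

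The other named genes that rose were the small GTPase ARL15 (5.03 ± 0.49), the transcription cofactor LBH (4.79 ± 0.58), the giant cadherin FAT3 (4.56 ± 0.45), and the membrane mucin MUC16 (4.54 ± 0.51). So did PPM1H (4.45 ± 0.31), CAMK1D (4.33 ± 0.27), ARID5B (4.29 ± 0.33), COL16A1 (4.15 ± 0.23) and TCF7L1 (4.06 ± 0.43). Those that fell were the transmembrane collagen COL13A1 (-4.86 ± 0.86), the galectin LGALS1 (-4.51 ± 0.36), PHLDA1 (-4.22 ± 0.45), the calcium-binding S100A9 (-4.21 ± 0.51), and the chromatin protein HMGA1 (-3.93 ± 0.22). Falls also came in the aminopeptidase ANPEP (-3.81 ± 0.56), the MAP kinase phosphatase DUSP4 (-3.77 ± 0.49), the T cell receptor segment TRBC2 (-3.44 ± 0.45) and calretinin, CALB2 (-3.44 ± 0.25). The adjusted p of these 18 genes lay between 3.07e-06 and 8.40e-04. The rule that chose these 24 genes required 1 direction in every phase and in both G1 clone pairs. The median span of the 12 that rose was 194.9 kb and that of the 12 that fell was 8.37 kb, against 25.8 kb over all tested genes.

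In all, 3544 of 12403 tested genes rose and 3292 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 2581 and 1902 of these changed at least 2-fold. The median span of the genes that rose was 56.9 kb and that of the genes that fell 15.1 kb. Among genes with spans over 300 kb, 354 of 437 rose and 6 fell. Their median log2 fold change was 2.02. Among those of up to 10 kb 519 of 3278 rose and 1240 fell, with a median of -0.42. Other ways of scaling the libraries moved the median log2 fold change of all genes from 0.02 to -0.10 (median-of-ratios) or -0.11 (quantiles). Fold changes are relative to that centre.

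**Figure D1:**
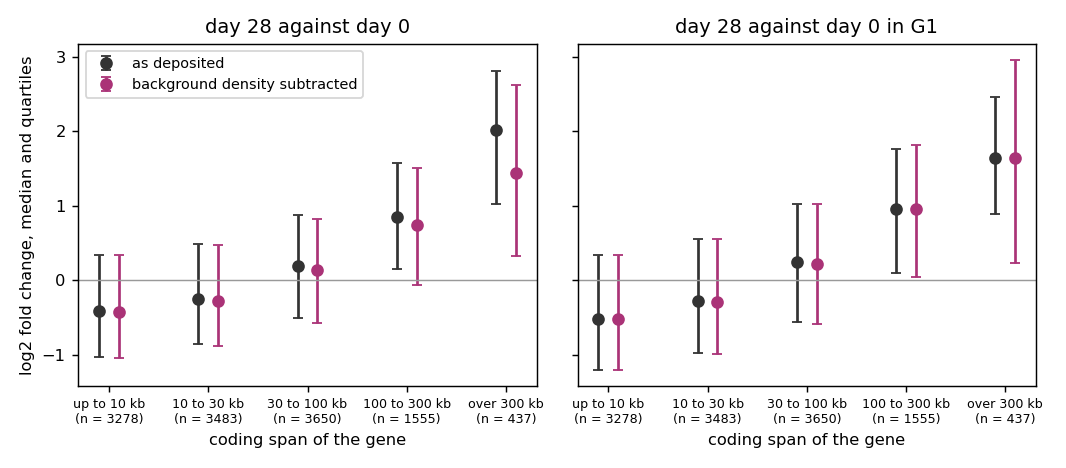
Median log2 fold change at day 28 against day 0 by coding span of the gene (kb), over all phases and in G1, with bars for the quartiles over genes, as deposited and with the background density of each library subtracted. The median over genes with spans above 300 kb was 2.02 over all phases (1.44 with the background subtracted) and 1.64 in G1 (1.65 with it subtracted).

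EGFR itself, the drug's target, rose by 1.75 ± 0.26 (SE, adjusted p = 3.02e-04, ENSG00000146648, chromosome 7, 55019278 to 55205617), from 12.86 ± 0.60 (SD, n = 5) to 14.69 ± 0.46 (SD, n = 4). The rise lay on its 5′ side. The 123 kb with exon 1 and intron 1 (chromosome 7, 55019278 to 55142356, 0.778% exonic) rose by 2.46 ± 0.40 (SE, limma adjusted p = 0.000363). The remaining 63.3 kb (55142357 to 55205617, 8.37% exonic) stood at -0.04 ± 0.18 (adjusted p = 0.863). This division was made after the data were examined. DUSP6, a phosphatase induced by ERK signalling, fell by 4.62 ± 0.62 (adjusted p = 1.77e-04, ENSG00000139318, chromosome 12, 89349254 to 89352039). The receptor kinase AXL fell by 2.09 ± 0.21 (adjusted p = 4.71e-05).

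**Figure D2:**
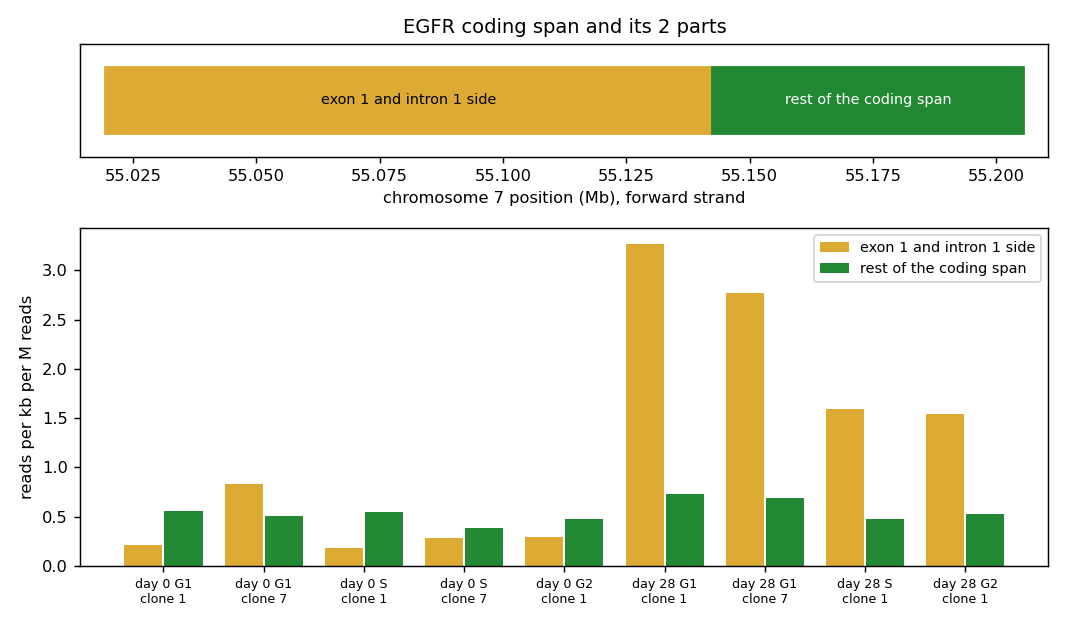
The EGFR coding span on chromosome 7 (position in Mb) divided into the exon 1 and intron 1 side and the rest, and the reads per kb per M reads in each part for each of the 9 libraries. The exon 1 and intron 1 side lay at 0.182 to 0.830 in the day 0 libraries and at 1.54 to 3.27 in the day 28 libraries, and the rest lay at 0.380 to 0.558 and 0.471 to 0.733.

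Of the other genes fixed in advance, the receptor kinase MET rose by 1.16 ± 0.24 (adjusted p = 0.00213). That call ended once trends with span, coding length and GC content were removed (0.48, adjusted p = 0.120). Cyclin B1, CCNB1, which drives mitotic entry, fell by 1.98 ± 0.34 (adjusted p = 7.66e-04), as did the proliferation antigen MKI67, at -1.94 ± 0.68 (adjusted p = 0.0305). The MKI67 call was lost without either day 0 G1 library (adjusted p = 0.0529 without clone 1, and a log2 fold change of -1.21 without clone 7). It was also lost without either day 28 G1 library (adjusted p = 0.0733 without clone 1, and a log2 fold change of -1.25 without clone 7), as the mean of the within-phase differences (0.0531), with quantile scaling (0.0578) and by voom (0.0684). No change passed the test for ERBB2 (0.36 ± 0.22), ERBB3 (0.60 ± 0.26), cyclin D1, CCND1 (-0.62 ± 0.27), or cyclin E2, CCNE2 (-0.52 ± 0.81). Neither CDK inhibitor passed it, with CDKN1A at 0.19 ± 0.45 and CDKN1B at -0.27 ± 0.24. CDT1 (-0.39 ± 0.52, adjusted p = 0.543) and GMNN (-0.99 ± 0.46, adjusted p = 0.0864), to which the reporter fragments can add reads, did not pass either. Both passed with the clone as a replicate block (-0.67, adjusted p = 0.0442, and -1.21, adjusted p = 0.00585) and in clone 1 alone (adjusted p = 0.0134 and 2.28e-04). CCND1 passed in clone 1 alone (-0.97, adjusted p = 0.00501), with median-of-ratios scaling (0.0451) and by voom (0.0421), and ERBB3 on a narrower span (0.0473). Some of these uncalled genes passed without 1 library. These were CCND1 without day 0 G1 clone 7 (adjusted p = 0.0339) and ERBB2 without the day 28 S library (0.0340). ERBB3 passed without day 0 S clone 1 (0.0414), day 0 G2 (0.0465) or day 28 G2 (0.0457). GMNN passed without day 0 G1 clone 7 (0.0150), day 0 S clone 7 (0.0420) or the day 28 S library (0.0394). SPRY4, an ERK feedback inhibitor, was too low to test (mean 4.28 on the log2 scale).

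Pooled over phases, genes of proliferation and of ERK signalling fell as lists. Each list was fixed before the data were examined and tested with camera against all other genes. Of 46 G2 and mitosis genes, 29 fell and 0 rose (30 and 0 adjusted over the list alone), with a median log2 fold change of -1.28 (adjusted p = 2.56e-07, and adjusted p = 0.657 with an estimated correlation). Among them were MAD2L1 (-2.42 ± 0.48), CENPA (-2.38 ± 0.48), TPX2 (-2.31 ± 0.37) and BIRC5 (-2.27 ± 0.44). Of 47 DNA replication genes, 22 fell and 1 rose (the same numbers adjusted over the list alone), with a median of -0.84 (adjusted p = 7.52e-05, and adjusted p = 0.727 with an estimated correlation). They include MCM6 (-2.09 ± 0.31), RRM2 (-1.91 ± 0.46), PRIM1 (-1.89 ± 0.38) and GINS2 (-1.87 ± 0.39). The list mean fell in G1 and G2 at day 28. In S its 12.69 lay between the day 0 values of 12.74 (clone 1) and 12.49 (clone 7). Of 24 tested ERK pathway targets, 16 fell and 3 rose (the same numbers adjusted over the list alone), with a median of -1.32 (adjusted p = 0.00126, and adjusted p = 0.498 with an estimated correlation). The ETS factor ETV5 fell by 2.45 ± 0.31 beside DUSP6, PHLDA1 and DUSP4. The ephrin receptor EPHA4 rose by 3.45 ± 0.34.

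Metabolic and translation genes fell together. The cholesterol pathway lost expression in 21 of 24 tested genes and gained it in 0 (22 and 0 adjusted over the list alone), with a median of -1.58 (adjusted p = 9.56e-09, and adjusted p = 0.498 with an estimated correlation). The thiolase ACAT2 fell by 2.55 ± 0.23, with the sterol-regulated INSIG1 at -2.46 ± 0.22. All but 1 of 48 cytosolic ribosomal protein genes fell (47, and 47 adjusted over the list alone), with a median of -1.31 (adjusted p = 2.04e-14, and adjusted p = 0.527 with an estimated correlation). RPL27 fell by 2.27 ± 0.23, with RPL7 at -2.19 ± 0.24. These genes are short, with a median span of 3.71 kb. Of 32 ribosome biogenesis genes 26 fell and 0 rose (26 and 0 adjusted over the list alone), with a median of -0.96 (adjusted p = 6.13e-08, and adjusted p = 0.527 with an estimated correlation). Among them were the small nucleolar ribonucleoprotein NHP2 (-1.81 ± 0.23) and nucleophosmin, NPM1 (-1.75 ± 0.25). Nuclear genes of the respiratory chain fell in 35 of 41 cases and rose in 0 (37 and 0 adjusted over the list alone), with a median of -1.13 (adjusted p = 1.62e-11, and adjusted p = 0.498 with an estimated correlation). They were led by the ATP synthase subunit ATP5F1A (-2.03 ± 0.17) and the succinate dehydrogenase subunit SDHC (-1.95 ± 0.28). Of 22 glycolysis genes 14 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -1.69 (adjusted p = 7.52e-05, and adjusted p = 0.498 with an estimated correlation). The glucose transporters went apart, SLC2A1 at -2.36 ± 0.19 and SLC2A3 at 2.50 ± 0.27. The enzymes TPI1 (-2.49 ± 0.25) and ENO1 (-2.43 ± 0.23) fell.

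Of 29 NRF2 targets, genes of the oxidative stress response, 14 fell and 2 rose (15 and 3 adjusted over the list alone), with a median of -0.85 (adjusted p = 0.00443, and adjusted p = 0.640 with an estimated correlation). They include the exporter ABCC2 (-2.65 ± 0.32) and the pentose phosphate enzyme PGD (-2.04 ± 0.21). This call was lost with quantile scaling (adjusted p = 0.293, median -0.38). Of 33 genes of the unfolded protein response and ATF4, 15 fell and 5 rose (the same numbers adjusted over the list alone), with a median of -0.51 (adjusted p = 0.0483, and adjusted p = 0.527 with an estimated correlation). Its members diverged: the stress cofactor NUPR1 rose by 4.33 ± 0.46 and the transcription factor ATF3 by 2.25 ± 0.42. The ATF4 target TRIB3 fell by 2.50 ± 0.37. The chaperone DNAJB9 also fell (-2.30 ± 0.75, adjusted p = 0.0215), a call lost without the day 0 G2 library (-1.20) or day 28 G1 clone 1 (adjusted p = 0.0528) and with trends removed (0.0721). The list's own call was lost with the clone as a replicate block (adjusted p = 0.0592). It was also lost without day 0 G1 clone 1 (adjusted p = 0.0538), day 0 S clone 7 (0.0647), day 0 G2 (0.0503), day 28 G1 clone 1 (0.0789) or day 28 S (0.0557), with the background subtracted (0.0655, median -0.51), with trends removed (0.229, median -0.48) and with median-of-ratios (0.0554, median -0.62) or quantile scaling (0.258, median -0.48).

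A few lists rose. Interferon-stimulated genes went up in 15 of 31 tested cases and down in 0 (14 and 0 adjusted over the list alone), with a median of 0.77 (adjusted p = 0.00300, and adjusted p = 0.640 with an estimated correlation). They were led by IFI44 (3.47 ± 0.45), IFI6 (3.45 ± 0.55) and the signal transducer STAT2 (2.18 ± 0.28). Targets of YAP and TEAD, effectors of the Hippo pathway, rose in 12 of 24 cases and fell in 3 (13 and 3 adjusted over the list alone), with a median of 0.64 (adjusted p = 0.0213, and adjusted p = 0.498 with an estimated correlation). The RNA-binding RBMS3 (4.88 ± 0.61), the phosphatase PTPN14 (3.35 ± 0.30), TEAD1 itself (3.29 ± 0.34) and CRIM1 (2.30 ± 0.33) rose. The median span in this list was 51.5 kb. The call was lost without day 0 G2 (adjusted p = 0.0579) or day 28 G2 (0.0592), and with span, length and GC trends removed (0.0651, median 0.55). The 13 mRNAs of the mitochondrial genome rose as a list, 4 of them by their own test and none lower (the same number adjusted over the list alone), with a median of 0.83 (adjusted p = 0.0417, and adjusted p = 0.763 with an estimated correlation). MT-ND6, the light-strand mRNA, rose by 3.27 ± 0.26 and MT-ND5 by 1.91 ± 0.38, both subunits of complex I. That call was lost with the clone as a replicate block (adjusted p = 0.0585). It was also lost without day 0 G1 clone 1 (adjusted p = 0.0974), day 0 S clone 1 (0.0711), day 0 G2 (0.0991), day 28 G1 clone 1 (0.0606), day 28 S (0.162) or day 28 G2 (0.0867). The mitochondrial share of reads in day 28 G1 clone 7 (8.61%) lay inside the day 0 range.

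**Figure D3:**
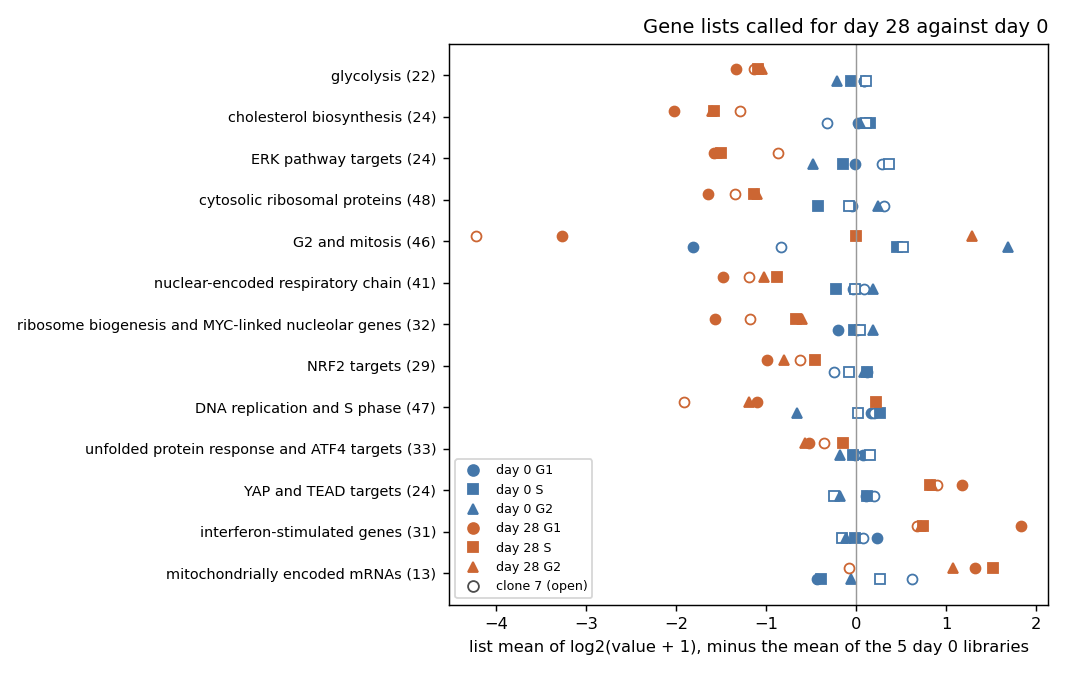
List means of log2(value + 1) per library minus the mean of the 5 day 0 libraries (log2 units, number of tested genes in parentheses), for the 13 lists with a call at day 28 against day 0. Blue symbols are day 0 and orange day 28 libraries, with circles for G1, squares for S, triangles for G2 and open symbols for clone 7. For cholesterol biosynthesis, respiratory chain and ribosomal protein genes each day 28 library lay below each day 0 library.

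The 20 remaining tested lists gave no call by camera. By fry, which asks whether members move on balance and not whether they move more than other genes, 7 of them passed: fatty acid oxidation (adjusted p = 3.22e-04), alveolar (0.00321), complement (0.00480), immediate early and heat shock (0.00547), receptor kinase (0.0118), translesion (0.0185) and quiescence genes (0.0288). Of the 13 lists with a camera call, mitosis (0.0830), DNA replication (0.136) and mitochondrial genes (0.0969) did not pass by fry. Of 17 receptor tyrosine kinases 7 rose and 4 fell, with a median of 0.60 (adjusted p = 0.293). The insulin receptor INSR rose by 2.81 ± 0.30, ERBB4 by 3.57 ± 0.60 and the IGF1 receptor IGF1R by 1.82 ± 0.25. ERBB4 lost its call with the background density subtracted (0.80, adjusted p = 0.682) and IGF1R with span, length and GC trends removed (0.31, adjusted p = 0.381). Of 19 mesenchymal genes 5 rose and 8 fell, with a median of -0.11 (adjusted p = 0.468). The actin-binding TAGLN rose by 3.66 ± 0.50. Beside VIM the matrix proteins TGFBI (-3.19 ± 0.18) and COL6A1 (-2.57 ± 0.41) fell. Of 28 epithelial genes 3 rose and 8 fell, with a median of -0.13 (adjusted p = 0.689). GRHL2, a transcription factor of epithelial identity, stood at 2.15 ± 0.23 and the adhesion protein EPCAM at -1.31 ± 0.19. Alveolar markers rose in 6 and fell in 2 of 14 cases, with a median of 0.59 (adjusted p = 0.353). CLIC5, a chloride channel of type 1 alveolar cells, rose by 4.77 ± 0.31. Of 9 mucin and secretory genes 2 rose and 4 fell, with a median of -0.47 (adjusted p = 0.734), MUC20 rising by 1.76 ± 0.27 where AGR2 fell. Of 9 complement genes 6 rose and 2 fell, with a median of 1.27 (adjusted p = 0.321). The protease C1S rose by 3.17 ± 0.58 and the inhibitor CD55 by 1.94 ± 0.18, and C3 fell by 2.24 ± 0.25. Of 19 MHC class I genes 2 rose and 7 fell, with a median of -0.23 (adjusted p = 0.468), HLA-F at 1.45 ± 0.23 and the proteasome activator PSME1 at -1.30 ± 0.19.

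Growth control lists were also split. Of 23 p53 targets 4 rose and 5 fell, with a median of -0.05 (adjusted p = 0.830). The apoptosis inhibitor TRIAP1 fell by 1.77 ± 0.35, with the death receptor FAS at -1.54 ± 0.28. Of 26 quiescence genes 7 rose and 2 fell, with a median of 0.23 (adjusted p = 0.353, and 0.0135 with span, length and GC trends removed). FOXO1 rose by 2.72 ± 0.54, FOXO3 by 2.19 ± 0.50 and ZBTB20 by 2.46 ± 0.40. Of 13 secreted factors of senescence 2 rose and 1 fell, with IL6 at 2.54 ± 0.44 and the protease PLAU at -2.44 ± 0.23. Their median was -0.09 while their mean was 0.24 and the test pointed up (adjusted p = 0.830). Of 20 persister and stem-like markers 6 rose and 5 fell, with a median of 0.09 (adjusted p = 0.877), SOX4 at 2.70 ± 0.31 and CD44 at -2.02 ± 0.36. Of 24 apoptosis regulators 5 rose and 5 fell, with a median of -0.03, a mean of 0.23 and a test pointing down (adjusted p = 0.975). BCL2, which blocks apoptosis, rose by 2.53 ± 0.41, as did BIM, BCL2L11, which promotes it, by 1.75 ± 0.38. TGF-beta and BMP targets rose in 7 and fell in 4 of 18 cases, with a median of 0.69 (adjusted p = 0.490). The activin antagonist FST rose by 3.45 ± 0.68 and SMAD6 by 2.57 ± 0.34. Of 9 Wnt targets 3 rose, AXIN2 by 2.32 ± 0.42, and 2 fell, with a median of 0.40 (adjusted p = 0.877).

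Among repair, stress and catabolic lists, 24 immediate early and heat shock genes included 6 that rose and 12 that fell, with a median of -0.50 (adjusted p = 0.249). The phosphatase DUSP1 stood at 2.68 ± 0.25, the cytokine inhibitor SOCS3 at -3.84 ± 0.75 and the chaperone HSPA8 at -2.49 ± 0.21. Of 21 fatty acid oxidation genes 5 rose and 12 fell, with a median of -0.74 (adjusted p = 0.0586), the carnitine transferase CPT1B at 2.12 ± 0.21 and HADHA at -1.58 ± 0.17. Of 35 lysosome and autophagy genes 5 rose and 9 fell, with a median of -0.27 (adjusted p = 0.468). Their regulator TFEB rose by 1.98 ± 0.43 and the kinase ULK1 by 1.59 ± 0.24. Of 40 homologous recombination and Fanconi genes 9 rose and 5 fell, with a median of -0.00 against a mean of 0.09 (test upward, adjusted p = 0.830). FANCC rose by 1.79 ± 0.27 and RAD51B by 2.22 ± 0.35. RAD51B had no call once span, length and GC trends were removed (0.03, adjusted p = 0.928). Of 8 mismatch repair genes 0 rose and 3 fell, with a median of -0.35 (adjusted p = 0.427, and 0.0372 with those trends removed), with MSH6 at -1.41 ± 0.30. Of 13 translesion and error-prone polymerase genes 6 rose and 1 fell, with a median of 0.64 (adjusted p = 0.133). POLN stood at 1.95 ± 0.25 and REV3L, the catalytic subunit of polymerase zeta, at 1.74 ± 0.24.

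Adjusted over the list alone, the higher and lower counts of these 20 lists were the same except for epithelial (3 and 7), MHC class I (1 and 6), p53 (4 and 3), and quiescence genes (7 and 1). The others that differed were persister (7 and 6), lysosome (5 and 6), apoptosis (5 and 4), recombination (8 and 3), mismatch repair (0 and 2) and mucin genes (2 and 5).

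Few markers of other cell types that a culture or gate might hold passed the filter. Of 20 leukocyte markers 1 passed the filter, the integrin ITGAM (1.22 ± 0.36, adjusted p = 0.0128, lost with span, length and GC trends removed at 0.75 and with quantile scaling at 0.75, adjusted p = 0.119). Of 17 fibroblast and endothelial markers 3 passed it: COL1A1 (0.38 ± 0.27, adjusted p = 0.253), PECAM1 (-2.50 ± 0.47, adjusted p = 0.00122) and CDH5 (-1.85 ± 0.49, adjusted p = 0.00828). Too few genes for a list test also passed among the histones that are made during replication (4 of 56), MHC class II (1 of 14) and APOBEC3 cytidine deaminases (4 of 7). The histone H2BC18 rose by 2.09 ± 0.50 (adjusted p = 0.00442), as did HLA-DMA by 1.47 ± 0.29 (adjusted p = 0.00165, lost on a narrower span at 0.93). APOBEC3C fell by 1.36 ± 0.21, and APOBEC3D rose by 1.70 ± 0.47 (adjusted p = 0.0101), a call lost without the day 28 S library (adjusted p = 0.0538) and with quantile scaling (1.09, adjusted p = 0.0663).

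Within G1 the same question was put to 2 libraries per day. PSG5 rose by 6.66 ± 0.80 (SE, 101-fold, adjusted p = 0.00274), LBH by 5.65 ± 0.88, SEMA5A by 5.57 ± 0.54 and ARL15 by 5.34 ± 0.83. TGM2 fell by 5.37 ± 0.74, with LGALS1 at -5.06 ± 0.54 and DUSP6 at -5.63 ± 0.85 (adjusted p = 0.00416). COL13A1 fell by 5.98 ± 1.36. This call was lost without either day 28 G1 library (adjusted p = 0.0885 without clone 1 and 0.0657 without clone 7) and by voom (0.0912). AGR2 fell by 5.62 ± 1.17, lost without clone 7 (0.0630). EGFR stood at 1.87 ± 0.42 (adjusted p = 0.0133). It lost its call without day 28 G1 clone 1 (adjusted p = 0.0808) or clone 7 (0.0554) and with span, length and GC trends removed (0.76). MET (1.41 ± 0.33) likewise lost it without clone 1 (adjusted p = 0.0715) and with those trends removed (0.63). In all 2462 genes rose and 2374 fell (limma, 6206 genes at an unadjusted p under 0.05), and 2515 or 3079 genes were called without day 28 G1 clone 1 or clone 7.

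Cell cycle lists fell in G1. All but 4 of 46 mitosis genes fell (42, and 45 adjusted over the list alone), with a median of -2.41 (adjusted p = 1.85e-14, and adjusted p = 0.575 with an estimated correlation). Among them were CENPA (-3.72 ± 0.39), the anaphase activator CDC20 (-3.66 ± 0.52), CCNB1 (-2.77 ± 0.45) and MKI67 (-3.84 ± 0.77, lost without day 28 G1 clone 7, adjusted p = 0.0561). DNA replication genes fell in 36 of 47 cases (39 adjusted over the list alone), with a median of -1.67 (adjusted p = 2.16e-12, and adjusted p = 0.575 with an estimated correlation). RRM2 fell by 3.22 ± 0.43, with PRIM1 at -2.83 ± 0.32. The ERK targets fell in 10 and rose in 1 of 24 cases (11 and 2 adjusted over the list alone), with a median of -1.44 (adjusted p = 0.00487, and adjusted p = 0.575 with an estimated correlation). PHLDA1 stood at -4.94 ± 0.62 and EPHA4 at 3.51 ± 0.58.

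The metabolic and ribosomal lists with a call in G1 went the same way as over all phases. Of these only glycolysis and NRF2 had members that rose (2 each). Cholesterol genes fell in 16 of 24 cases (18 adjusted over the list alone), with a median of -1.50 (adjusted p = 3.40e-06). INSIG1 fell by 2.56 ± 0.32. Respiratory chain genes fell in 32 of 41 (36 adjusted over the list alone), with a median of -1.23 (adjusted p = 3.97e-12). ATP5MC3 fell by 2.38 ± 0.26, with UQCRFS1 at -2.28 ± 0.25. Glycolysis genes fell in 15 of 22 (15 adjusted over the list alone), with a median of -1.88 (adjusted p = 5.97e-05). TPI1 fell by 2.99 ± 0.33 while the regulator PFKFB4 rose by 1.60 ± 0.36 (lost without day 28 G1 clone 1, adjusted p = 0.0616). Ribosomal protein genes fell in 46 of 48 (48 adjusted over the list alone), with a median of -1.65 (adjusted p = 7.95e-15). RPL27 fell by 2.68 ± 0.26, with RPL7 at -2.32 ± 0.38. Ribosome biogenesis genes fell in 23 of 32 (25 adjusted over the list alone), with a median of -1.21 (adjusted p = 2.79e-09). NHP2 fell by 2.42 ± 0.24, with BOP1 at -2.41 ± 0.25. The glycolysis list stood at adjusted p = 0.567 with an estimated correlation. The other 4 stood at adjusted p = 0.575 with an estimated correlation.

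In G1, NRF2 targets fell in 7 of 29 (7 adjusted over the list alone), with a median of -0.69 (adjusted p = 0.0319, and adjusted p = 0.653 with an estimated correlation). PGD fell by 2.44 ± 0.24. The call for the list was lost without day 0 G1 clone 1 (adjusted p = 0.139) or day 28 G1 clone 1 (0.229) and with quantile scaling (0.382, median -0.51). Interferon-stimulated genes rose in 11 of 31 (11 adjusted over the list alone), with a median of 1.04 (adjusted p = 0.00196, and adjusted p = 0.653 with an estimated correlation). IFI44 rose by 3.77 ± 0.72 and STAT2 by 2.69 ± 0.39. This call was lost without day 28 G1 clone 1, where the median was 0.56. With the clone as a replicate block the YAP list (adjusted p = 0.0473 against 0.0792) and the unfolded protein list (0.0472 against 0.0530) also passed. By fry 5 lists without a camera call in G1 passed, fatty acid oxidation (adjusted p = 0.0208) and the mesenchymal, unfolded protein, immediate early and complement lists (0.0428 each). The interferon (0.137) and NRF2 lists (0.121) did not pass by fry.

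In S phase, 1 day 28 library stood against 2 at day 0, so the lone library was assumed to vary like the others. GAB2 rose by 6.58 ± 0.91 (SE, adjusted p = 0.0271), SEMA5A by 5.06 ± 0.66, ARL15 by 5.21 ± 1.02 and FAT3 by 5.09 ± 0.93. The calls of ARL15 (3.49, adjusted p = 0.0511) and FAT3 (2.58) ended once span, length and GC trends were removed. That of ARL15 also ended without day 0 S clone 1 (adjusted p = 0.0688) and that of FAT3 with the background subtracted (5.80, adjusted p = 0.0506). VIM fell by 7.05 ± 0.58 (adjusted p = 0.0229), with AGR2 at -7.08 ± 1.43, TGM2 at -5.91 ± 0.90, the chloride channel ANO1 at -4.53 ± 0.79, DUSP6 at -4.60 ± 1.04 and AXL at -2.60 ± 0.34. The DUSP6 call was lost without day 0 S clone 1 (adjusted p = 0.0535), with the background subtracted (-4.66, adjusted p = 0.0540), on a narrower span (-4.28, adjusted p = 0.0563) and by voom (0.0620), and that of AGR2 by voom (0.0732). EGFR stood at 1.82 ± 0.52 (adjusted p = 0.0695). It passed with the clone as a replicate block (0.0432), without the filter (0.0378) and with quantile scaling (0.0482). In all 545 genes rose and 359 fell (limma, 3928 at an unadjusted p under 0.05). As many as 1938 genes were called with the clone as a replicate block, 544 with the background subtracted (280 rose and 264 fell) and 501 on narrower spans. Median-of-ratios scaling gave 538 higher and 614 lower genes and quantile scaling 425 and 419. No gene was called (limma) without day 0 S clone 7 (2366 at an unadjusted p under 0.05), without day 28 G1 clone 1 (3972) or without day 28 G1 clone 7 (3974). The count was 181 without day 0 S clone 1, and 1654 and 1638 without day 0 G1 clone 1 or clone 7. EGFR passed without either of these last libraries (adjusted p = 0.0206 and 0.0210).

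G2 had 1 library on each day, so its differences have no replicate check, and by the plan none was tested. At day 28 GAB2 lay 5.77 log2 units above day 0, SEMA5A 4.29, PSG5 3.18 and EGFR 1.40. TGM2 stood at -7.17, AGR2 at -4.21, LGALS1 at -3.55, VIM at -2.80, DUSP6 at -2.64, INSIG1 at -2.44, CCNB1 at -1.20 and MKI67 at -0.23. Among 10000 random lists matched on size and mean expression, the medians of the cholesterol (-1.71), ribosomal protein (-1.36), respiratory chain (-1.29) and ERK target lists (-1.07) lay at percentile 0, as did glycolysis (-1.22), and NRF2 (-0.93) at 1. DNA replication genes (-0.48) lay at percentile 3.05 and mitosis genes (-0.37) at 19.8, while YAP targets (1.03) and mitochondrial mRNAs (0.94) lay at 100. Translesion (0.85), TGF-beta (0.81), complement (0.76) and recombination genes (0.38) lay at percentile 98.6, 98.4, 98 and 97.2, and interferon-stimulated genes (0.58) at 90.0. These percentiles place a list among the genes of 2 libraries and test no effect of the day.

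Sorting by phase was the other axis of the design, and at day 0 the S and G2 gates were compared with G1. Mitosis genes were higher in S, by a median of 1.80 over the list (adjusted p = 1.03e-66, and adjusted p = 0.873 with an estimated correlation), with 39 of 46 passing when adjusted over the list alone and 0 over all genes. The kinase PLK1 stood at 2.97 ± 0.71 (SE), CKAP2L at 2.56 ± 0.55 and the topoisomerase TOP2A at 2.50 ± 0.71. Upward shifts also passed for cholesterol genes (0.30, adjusted p = 0.00283) and recombination genes (0.28, adjusted p = 0.00468), each at adjusted p = 0.873 with an estimated correlation. FANCD2 stood at 1.09 ± 0.34. Downward shifts passed for ribosomal protein (-0.38, adjusted p = 6.63e-09) and mucin genes (-0.74, adjusted p = 0.00355), each at adjusted p = 0.873 with an estimated correlation. RPL38 stood at -0.66 ± 0.30 and S100P at -0.97 ± 0.39. No member (0) of these 4 lists passed, over all genes or adjusted over the list alone.

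The 4 other calls in S at day 0 were fragile to single libraries. The recombination list was lost without day 0 G1 clone 1 (adjusted p = 0.787), cholesterol and mucins without day 0 G1 clone 7 (0.575 and 0.100). All 4 were lost without day 0 S clone 1 (0.0579, 0.0579, 0.0579 and 0.384). The DNA replication list did not differ by its test (median 0.10, mean -0.04, adjusted p = 0.558). No single gene passed in S against G1 (limma, 446 at an unadjusted p under 0.05, and 0 by voom). By fry 0 of the 5 called lists passed (lowest adjusted p = 0.655).

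In the day 0 G2 library, mitosis genes stood higher than in G1, with a median of 3.01 (adjusted p = 3.35e-62, and adjusted p = 0.457 with an estimated correlation). Of these genes 45 passed adjusted over the list alone. The kinesin KIF20A stood at 4.61 ± 1.07 (SE), PLK1 at 4.57 ± 0.86 and AURKA at 4.06 ± 0.42 (adjusted p = 0.0735). DNA replication genes were lower, with a median of -0.72 (adjusted p = 3.50e-13, and adjusted p = 0.499 with an estimated correlation). Of these genes 12 passed adjusted over the list alone. The S phase activator E2F1 stood at -3.09 ± 0.53 and the helicase subunit MCM5 at -2.41 ± 0.38. The mucin list was lower too (median -0.94, adjusted p = 2.02e-04, and adjusted p = 0.481 with an estimated correlation, MUC16 at -2.99 ± 1.06). No single gene passed over all genes (limma, 782 at an unadjusted p under 0.05, and 45 by voom). Without day 0 G1 clone 7, 6 passed, among them PLK1 (adjusted p = 0.0365), TOP2A (0.0366) and AURKA (0.0423).

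Other calls of this comparison were p53 targets (median -0.32, adjusted p = 0.0102) and senescence factors (-0.62, adjusted p = 0.0102), which share GDF15 (-3.78 ± 0.76). Each stood at adjusted p = 0.457 with an estimated correlation. Persister markers (-0.45, adjusted p = 0.0321) and YAP targets (-0.26, adjusted p = 0.0137) were lower too, again at adjusted p = 0.457 with an estimated correlation. The aldehyde dehydrogenase ALDH3A1 stood at -1.21 ± 0.70 and the clotting initiator F3 at -1.58 ± 0.43. ERK targets were lower as well (-0.58, adjusted p = 0.0102, and adjusted p = 0.499 with an estimated correlation), with EGR1 at -1.71 ± 0.80. Lysosome genes were lower (-0.27, adjusted p = 0.0137) and ribosome biogenesis genes higher (0.23, adjusted p = 0.0137), both at adjusted p = 0.588 with an estimated correlation. TFEB stood at -3.08 ± 0.56 and ODC1 at 0.78 ± 0.38.

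Among these 7 lists of G2 against G1 at day 0, adjusted over the list alone, 1 member each of the p53, senescence and lysosome lists passed, and 0 of the others. By fry 0 of the 10 lists called in this comparison passed (lowest adjusted p = 0.366). These 7 calls were lost without day 0 G1 clone 1 (adjusted p = 0.0714 for p53, 0.455 for senescence, 0.455 for lysosome genes, 0.186 for persister markers, 0.0568 for YAP targets, 0.0825 for ERK targets and 0.278 for ribosome biogenesis). The persister call was also lost with trends removed (0.185, median -0.33) and on narrower spans (0.0829, median -0.33), and that of ribosome biogenesis with quantile scaling (0.128, median 0.07). The ERK (0.143, median -0.24), lysosome (0.0938, median -0.12) and persister calls (0.0865, median -0.38) were lost with the clone as a replicate block and trends removed. With the clone as a replicate block 10 more lists passed, from interferon-stimulated genes (adjusted p = 9.20e-04), ribosomal proteins (8.15e-04) and the respiratory chain (0.00150) to mesenchymal (0.0123), complement (0.0154), TGF-beta (0.0163), epithelial (0.0207), receptor kinase (0.0366), glycolysis (0.0481) and mismatch repair genes (0.0480).

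The comparisons of S and G2 with G1 after 28 days of drug asked how far apart the phases lay in treated cells. In S against G1, 90 genes were higher and 23 lower (limma, 2171 at an unadjusted p under 0.05). The mitotic genes DEPDC1 (5.67 ± 0.60, SE, adjusted p = 0.0342), FAM83D (5.48 ± 0.54), the kinesin KIF18B (4.74 ± 0.57) and the kinase AURKB (4.71 ± 0.71) rose. So did RRM2 (3.61 ± 0.53), PRIM1 (2.82 ± 0.39) and thymidine kinase, TK1 (2.67 ± 0.39). The keratin KRT13 (-3.76 ± 0.58), PKD1L2 (-3.68 ± 0.44), BCAS1 (-3.63 ± 0.56) and the interferon-induced GTPase GBP2 (-3.03 ± 0.43) fell. Every one of these calls ended without day 28 G1 clone 7, when 0 genes passed (limma, 1533 at an unadjusted p under 0.05). Those of AURKB, PKD1L2, BCAS1 and GBP2 also ended without clone 1 (adjusted p = 0.0533, 0.0587, 0.0907 and 0.0731). On narrower spans 11 genes passed, and DEPDC1, RRM2 and GBP2 (adjusted p = 0.0557 each), PRIM1 (0.0564), TK1 (0.0594), AURKB (0.0598), BCAS1 (0.0741), PKD1L2 (0.104) and KRT13 (0.159) did not. With the clone as a replicate block AURKB (adjusted p = 0.0558) and KRT13 (0.0548) did not pass.

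As lists, mitosis genes lay higher in S at day 28 by a median of 3.82, with 28 of 46 passing (45 adjusted over the list alone, adjusted p = 5.99e-44). DNA replication genes lay higher by 1.76, with 6 of 47 passing (38 adjusted over the list alone, adjusted p = 1.07e-24). For recombination genes the median was 1.42, with 2 of 40 passing (24 adjusted over the list alone, adjusted p = 6.86e-11). Each of the 3 stood at adjusted p = 0.591 with an estimated correlation. No member passed over all genes in the ribosome biogenesis list (0.71, 6 higher adjusted over the list alone, adjusted p = 9.72e-07) or the respiratory chain list (0.45, 0 adjusted over the list alone, adjusted p = 2.04e-04). Both rose as lists, at adjusted p = 0.591 with an estimated correlation, with COX5A at 1.35 ± 0.42. Ribosomal proteins were higher (0.38, adjusted p = 0.00542, and adjusted p = 0.708 with an estimated correlation), with 0 members passing and RPL35 at 0.88 ± 0.37.

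Lists that fell in S at day 28 were lysosome genes (-0.68, 1 higher and 2 lower adjusted over the list alone, adjusted p = 1.57e-04), mucins (-1.92, 1 lower adjusted over the list alone, adjusted p = 0.00671) and mesenchymal genes (-0.56, 2 lower adjusted over the list alone, adjusted p = 0.0441). Each stood at adjusted p = 0.591 with an estimated correlation and had 0 members past the test over all genes, with the sialidase NEU1 at -2.39 ± 0.47. Interferon-stimulated genes were lower (-0.34, adjusted p = 0.0166, and adjusted p = 0.653 with an estimated correlation), with GBP2 the 1 member past the test (3 adjusted over the list alone). Without day 28 G1 clone 1 the interferon (adjusted p = 0.845), ribosomal protein (0.236) and mesenchymal calls (0.162) were lost. The last was also lost without day 0 G1 clone 1 (0.0579) or clone 7 (0.0588). With trends removed the ribosomal protein (0.163, median 0.23) and mesenchymal calls (0.0560, median -0.55) were lost. The clone as a replicate block added epithelial (adjusted p = 0.0466), quiescence (0.0128) and senescence genes (0.0158). By fry 0 of the 10 called lists passed (lowest adjusted p = 0.130).

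In the day 28 G2 library 222 genes were higher than in G1 and 141 lower (limma, 2615 at an unadjusted p under 0.05). KIF20A rose by 8.05 ± 1.07 (SE, adjusted p = 0.0109), DEPDC1 by 7.88 ± 0.60, FAM83D by 7.24 ± 0.54, TOP2A by 6.45 ± 0.87, CENPA by 6.72 ± 0.48, MKI67 by 6.26 ± 0.94 and CCNB1 by 4.77 ± 0.55. KRT13 fell by 5.15 ± 0.58 (adjusted p = 0.00704), with the tetraspanin TSPAN1 at -4.18 ± 0.75, the plasminogen activator PLAT at -4.14 ± 0.82 and the erythropoietin receptor EPOR at -4.00 ± 0.43. Without day 28 G1 clone 7, 59 genes passed, and KIF20A (adjusted p = 0.0746), TOP2A (0.115), MKI67 (0.113), CCNB1 (0.0777), TSPAN1 (0.161), PLAT (0.162) and EPOR (0.0641) did not. Without clone 1, 237 passed, with TOP2A (0.0611) and TSPAN1 (0.0578) lost. PLAT was also lost without day 0 G1 clone 1 (0.0524) or clone 7 (0.0514), on a narrower span (-3.70, adjusted p = 0.0631) and by voom (0.123), and KRT13 on a narrower span (-5.12, adjusted p = 0.0568). With the background density subtracted 256 genes were higher and 347 lower, and with the clone as a replicate block 561 genes were called.

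Of 46 mitosis genes 44 passed higher in G2 at day 28 (46 adjusted over the list alone), with a median of 5.07 (adjusted p = 7.54e-50, and adjusted p = 0.869 with an estimated correlation). DNA replication genes had 1 member higher and 1 lower (4 and 3 adjusted over the list alone), with a median of 0.56 and RRM2 at 2.07 ± 0.53 (adjusted p = 0.0878). The list had a call (adjusted p = 0.0186, and adjusted p = 0.951 with an estimated correlation). It was lost with the clone as a replicate block (adjusted p = 0.165) and without day 28 G1 clone 7 (0.604). Recombination genes were higher (0.80, 7 adjusted over the list alone, adjusted p = 0.00100), with the helicase BLM at 2.11 ± 0.54. So were ribosome biogenesis (0.79, 3 adjusted over the list alone, adjusted p = 6.54e-07) and respiratory chain genes (0.35, 0 adjusted over the list alone, adjusted p = 0.0251), with COX5A at 1.20 ± 0.42. These 3 lists stood at adjusted p = 0.869 with an estimated correlation. Ribosomal protein genes were higher (0.37, adjusted p = 0.00638, and adjusted p = 0.894 with an estimated correlation), with 0 members passing and RPL35 at 1.05 ± 0.37.

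Lower in G2 at day 28 were lysosome (-0.73, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.00152) and mucin genes (-1.67, 1 lower adjusted over the list alone, adjusted p = 0.00751). Each stood at adjusted p = 0.869 with an estimated correlation. Interferon (-0.47, 5 lower adjusted over the list alone, adjusted p = 0.0159) and senescence genes (-0.89, 4 lower adjusted over the list alone, adjusted p = 0.0431) were lower too, both at adjusted p = 0.869 with an estimated correlation, with PLAU at -1.68 ± 0.37. Over all genes 1 member passed in each of the ribosome biogenesis (BOP1, 1.65 ± 0.30), lysosome (WIPI1, -2.30 ± 0.39), mucin (MUC20, -2.61 ± 0.38) and interferon lists (IFIT2, -1.94 ± 0.36). Each of these 4 genes lost its call without day 28 G1 clone 1 (adjusted p = 0.0765, 0.0657, 0.0542 and 0.107) or clone 7 (0.0777, 0.141, 0.110 and 0.131). BOP1 and IFIT2 also lost it without day 0 S clone 1 (0.0828 and 0.0778) or clone 7 (0.0819 and 0.0779). Without day 28 G1 clone 1 the interferon (0.695), respiratory (0.355), ribosomal protein (0.188) and senescence lists (0.108) lost theirs. The senescence list also lost its call with the background subtracted (0.122, median -0.91), on narrower spans (0.102, median -0.80), with quantile scaling (0.0770) and, narrowly, with trends removed (median -0.99). The respiratory list lost its call with trends removed (0.103, median 0.30) and on narrower spans (0.0889, median 0.30), and the ribosomal protein list with quantile scaling (0.127, median 0.16). The clone as a replicate block added complement genes (adjusted p = 0.0306). By fry 0 of the 10 called lists passed (lowest adjusted p = 0.108).

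**Figure D4:**
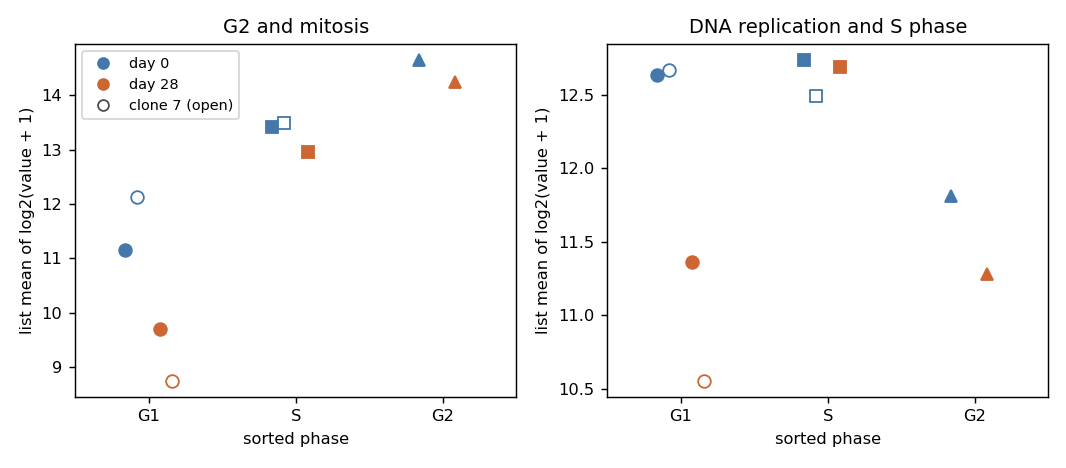
List mean of log2(value + 1) of 46 G2 and mitosis genes and of 47 DNA replication genes in each of the 9 libraries by sorted phase, blue for day 0 and orange for day 28, open symbols for clone 7. The mitosis mean in G1 was 11.15 and 12.14 at day 0 and 9.70 and 8.75 at day 28, against 14.65 and 14.25 in G2.

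Whether the response to the drug differed between phases was tested by the day-by-phase term, S and G2 against G1. The day effect on mitosis and DNA replication genes lay higher in S and G2 than in G1, by medians of 1.97 (38 of 46 adjusted over the list alone, adjusted p = 3.55e-29) and 1.52 (35 of 47 adjusted over the list alone, adjusted p = 3.08e-27). Both stood at adjusted p = 0.761 with an estimated correlation. MKI67 stood at 3.52 ± 0.93 (SE, adjusted p = 0.257), the securin PTTG1 at 3.03 ± 0.63, CCNB1 at 1.48 ± 0.55, MCM10 at 2.51 ± 0.49 and RRM2 at 2.44 ± 0.60. Recombination genes, with the nuclease EXO1 at 2.78 ± 0.44 and RAD54L at 2.23 ± 0.55, differed by 1.01 (9 of 40 adjusted over the list alone, adjusted p = 4.68e-08). Ribosome biogenesis genes differed by 0.48 (3 of 32 adjusted over the list alone, adjusted p = 7.38e-06), with BOP1 at 1.68 ± 0.33. Ribosomal protein genes differed by 0.60 (0 adjusted over the list alone, adjusted p = 1.33e-06, RPS15 at 1.07 ± 0.34) and respiratory chain genes by 0.40 (0 adjusted over the list alone, adjusted p = 7.05e-04, COX6A1 at 1.13 ± 0.65). Lysosome genes went the other way at -0.44 (1 adjusted over the list alone, adjusted p = 0.00264, WIPI1 at -1.93 ± 0.41). The mitochondrial mRNAs stood at 0.91 (0 adjusted over the list alone, adjusted p = 0.0293, MT-ND2 at 1.33 ± 1.01). These 6 lists also stood at adjusted p = 0.761 with an estimated correlation.

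No single gene passed for this term (limma, 1382 at an unadjusted p under 0.05, and 0 by voom). Without day 28 G1 clone 1, 56 passed, among them EXO1 (adjusted p = 0.0328), RAD54L (0.0328) and RRM2 (0.0492). The lysosome list lost its call without day 0 G1 clone 7 (adjusted p = 0.0976), day 28 G1 clone 7 (0.199) or day 28 S (0.185). The mitochondrial list lost it without day 0 G1 clone 7 (0.510), day 0 S clone 1 (0.103), day 28 G1 clone 7 (0.772) or day 28 S (0.288). It was also lost with trends removed (0.106, median 0.73), with the clone as a replicate block and trends removed (0.0848, median 0.76) and with quantile scaling (0.274, median 0.53). The respiratory list lost it without day 28 G1 clone 1 (0.106) or day 28 S (0.466) and the ribosomal protein list without day 28 S (0.0782). With the clone as a replicate block the interferon list also passed (adjusted p = 0.0135 against 0.0764). By fry 0 of the 8 called lists passed (lowest adjusted p = 0.451).

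The clones were compared across days and phases, with 3 libraries of clone 7 against 6 of clone 1. In clone 7 the X-linked germline gene VCX was higher by 4.21 ± 0.33 (SE, 18.5-fold, adjusted p = 2.25e-04), MAMDC2 by 2.95 ± 0.25, the ribosomal protein RPL41 by 2.77 ± 0.26 and the calpain CAPN8 by 2.22 ± 0.24. The call of CAPN8 was lost without day 0 S clone 7 (adjusted p = 0.0516). VCX and RPL41 belong to families of near-identical copies, so their reads can be split. ANKFY1, an endosomal protein, was lower by 3.43 ± 0.43. That call was lost without day 0 G1 clone 1 (adjusted p = 0.130) or day 28 G1 clone 1 (0.0621). CDT1 (-1.79 ± 0.29), part of the reporter, the TGF-beta pseudoreceptor BAMBI (-1.58 ± 0.24) and GRAMD2A (-1.61 ± 0.27) were also lower. Each was lost without day 0 G1 clone 1 (adjusted p = 0.200, 0.193 and 0.233), day 0 S clone 1 (0.0650, 0.0746 and 0.134), day 0 S clone 7 (0.125, 0.325 and 0.225) or day 28 G1 clone 1 (0.0720, 0.0621 and 0.125). CDT1 and BAMBI were lost without day 28 S (0.0673 and 0.0537), and CDT1 and GRAMD2A were lost without day 0 G2 (0.0571 and 0.0570) or day 28 G2 (0.0539 and 0.0539). Both were also lost with the background subtracted (-1.79, adjusted p = 0.0517, and -1.63, adjusted p = 0.0596), and GRAMD2A on a narrower span (-1.91, adjusted p = 0.0626) and with quantile scaling (0.0583).

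In all 48 genes were higher and 28 lower in clone 7 (limma, 1936 at an unadjusted p under 0.05). The count rested on single libraries. As few as 9 genes passed without day 0 G1 clone 1, 222 without day 0 G1 clone 7, 18 and 9 without day 0 S clone 1 and clone 7, and 33 without day 0 G2. There were 16 and 332 without day 28 G1 clone 1 and clone 7, 30 without day 28 S and 34 without day 28 G2. Quantile scaling gave 17 higher and 15 lower genes.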

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

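The division of spans, the background over olfactory receptor genes and every test in this part were chosen after the results they bear on had been seen, so they can exclude an explanation but not establish one. Other groupings of the libraries were tried as well: of 99 splits into 4 and 5 libraries only 1, the true one, called as many as 6836 genes (the highest other called 2945), and of 83 splits into 3 and 6 only 1 called as many as 76 (the highest other called 30). These were the splits that could be fitted of the 100 drawn and of all 84, since 1 of each followed the phases. A split that mixes days or clones puts their difference into the spread, so it calls few genes in any case. The 2945 came from 4 day 0 libraries against the rest. The splits therefore give no evidence for or against chance.

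Genes with spans above 300 kb took a larger share of reads at day 28, and reads appeared in olfactory receptor genes, which lie outside the comparisons, at 0.00787 (G1 clone 1), 0.00769 (G1 clone 7), 0.0120 (S) and 0.0258 (G2) reads per kb per M reads, above each day 0 library (mean 0.0133 ± 0.00854 SD, n = 4, against 0.00247 ± 0.00153, n = 5). An even background of reads from DNA or unspliced RNA was argued against as the whole cause in G1, where the lower quartile over these genes of the gain in read density was 1.62 times the gain over olfactory receptor genes, but in S and G2 the lower of the quartiles was 0.967 times it, so there a background may carry part of the rise. In 101 such genes with a narrower coding span, the part before it gained a median of 1.49 log2 units more than the rest (quartiles 0.29 to 2.25, background subtracted). The rest itself stood higher at day 28 by a median of 1.01. More intron reads go with this, but that part was chosen to be less exonic than the rest. The difference therefore cannot tell introns near the start from others. Whether drug-treated cells transcribe the starts of long genes more, end transcription early or leak nuclear RNA was not tested. The rise of a long gene may therefore hold intron reads beside those of its mRNA.

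EGFR rose on its exon 1 and intron 1 side by 2.46 log2 units, in reads that the fold change of the whole gene does not set apart. An even background was argued against, since the gain there was at least 56.1 times the gain over olfactory receptor genes in each phase. More gene copies or more full-length mRNA were argued against, since the rest of the span stood at -0.0403. A new transcript that ends in intron 1, a truncated product, and a higher start rate with early termination all stay open. So does a cause common to many genes. In 733 of 944 genes with a narrower coding span, the part before it gained more than the rest (median difference 0.95, quartiles 0.10 and 1.89). That part was chosen to be less exonic than the rest, so these genes do not show where in the gene the gain lay. Reads that cross the exon junctions, or long reads, would tell these explanations apart.

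The day effect on the mitosis genes was lower in G1 than in S and G2 by a median of 1.97, and that on DNA replication genes by 1.52, a difference between phases called by camera for the day-by-phase term (adjusted p = 0.761 with an estimated correlation). In clone 1 the G1 values were 8.44% of those in G2 at day 0 and 4.06% at day 28 (medians over 46 genes). G2 cells in the day 0 G1 gate could account for it, but a single share would give 1 excess for all genes, and the excess had a median of 4.42 points with quartiles of 2.01 and 7.07. With 1 G2 library per day this stays open. Trends with span, coding length and GC content were argued against, since the median was 2.04 with them removed and the clone as a replicate block, and a deeper cell cycle exit of treated G1 cells was not tested.

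The same term differed for recombination genes by a median of 1.01, for mitochondrial mRNAs by 0.91, for ribosomal protein genes by 0.60, for ribosome biogenesis genes by 0.48, for respiratory chain genes by 0.40 and for lysosome genes by -0.44. Each stood at adjusted p = 0.761 with an estimated correlation, and the mitochondrial, ribosomal protein, respiratory chain and lysosome calls were also lost without single libraries.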

How the results depend on the processing

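Of 260 results for named genes 196 passed their test. Of these, 163 kept direction and call under every setting other than a left-out library, and 146 without each library in turn, while 37 of the 64 that did not pass stayed so under every setting other than a left-out library. The count for day 28 against day 0 ran from 5714 to 8386 under all settings. With trends removed 4720 of the main 6836 calls were kept, 4660 with the same sign. In S against G1 at day 28 the clone as a replicate block ended the call of RAD51AP1 (adjusted p = 0.0553) and gave calls to NOP56 (0.0448), BOP1 (0.0448) and VIM (0.0438), and in G2 against G1 at day 28 to E2F1 (0.0373). The planned count tests (edgeR and DESeq2) were not run. Quantile scaling, voom, narrower spans, the background subtraction and the removal of trends were chosen after seeing the data. By simulation with a fixed dispersion of 0.05 the comparisons with 1 library in a group found 5% to 22% of 2-fold changes. The share in the data can be lower, so a list of genes without a call there is no evidence of no change. The depth of 8.83 M reads in day 0 G1 clone 7 sets the filter. The cause of the changes below was not tested, apart from settings that drop libraries or genes by their construction.

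For day 28 in S the main 904 genes became 2317 without the filter, 544 with the background subtracted, 501 on narrower spans, 1741 by voom, 1938 with the clone as a replicate block, and 1800 with the block and trends removed, with 248 higher and 428 lower genes when only the trends were removed, and the cause was not tested. For G2 against G1 at day 0 the main 0 became 33 without the filter, 45 by voom and 9 with the block and trends removed. For S against G1 at day 28 the main 113 became 171 by median-of-ratios, 277 without the filter, 362 by quantiles, 204 with trends removed, 11 on narrower spans, 244 by voom and 396 with the block and trends removed. For G2 against G1 at day 28 the main 363 became 684 without the filter, 684 by quantiles, 603 with the background subtracted, 670 by voom, 561 with the block and 944 with the block and trends removed. For the day-by-phase term the main 0 became 32 with the block and trends removed, and for the clones the main 76 became 32 by quantiles, 32 with the background subtracted, 37 on narrower spans and 142 by voom. Of the 66 list calls 0 were left with an estimated correlation. By fry 30 of all 231 list tests passed, and these include lists without a camera call. Counted over lists and settings, list calls were kept 432 times and lost 96 times (66 with the estimated correlation), and without single libraries kept 514 and lost 50 times.

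Without single libraries the counts ranged from 2515 to 4851 for day 28 in G1, from 0 to 1654 for day 28 in S, from 0 to 6 for G2 against G1 at day 0, from 0 to 156 for S against G1 at day 28, from 59 to 415 for G2 against G1 at day 28, from 0 to 56 for the day-by-phase term and from 9 to 332 for the clones.

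Signs turned for a few results of day 28 against day 0, and the cause was not tested. CDKN1A (0.19) stood at -0.16 in clone 1 alone, -0.37 by quantiles and -0.11 by voom, and from -0.05 to 0.47 without single libraries. CDKN1B (-0.27) stood at 0.0307 in clone 1 alone, 0.27 with trends removed and 0.25 with the block as well. MT-CO2 (1.04) stood at -0.0235 by quantiles. Without single libraries CCNE2 ranged from -1.84 to 0.51 and CDT1 from -0.84 to 0.21.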

Other observations

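This part was chosen after its values were seen. PSG5 was not alone among the pregnancy-specific glycoproteins, a cluster of placental genes on chromosome 19. Of 10 such genes in the file 4 were tested, and PSG1 rose by 6.54 ± 0.74 (SE, limma adjusted p = 7.30e-05), PSG4 by 5.62 ± 0.57 (adjusted p = 4.51e-05) and PSG9 by 5.28 ± 0.62 (adjusted p = 9.03e-05) beside PSG5. In 9 of the 10, all but PSG7, every day 28 library lay above every day 0 library, an order that chance gives in 0.794% of cases per gene and that 20.9% of tested genes showed. PSG1 went from 0.481 reads per M reads over the day 0 libraries to 45.5 over the day 28 libraries. These genes are near-identical in sequence, so reads of 1 member can be placed in another.

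Among mitochondrial mRNAs the light-strand MT-ND6 stood apart. Its density was 19.6 to 40.8 reads per kb per M reads in the day 0 libraries and 262 to 413 in the day 28 libraries, a log2 fold change of 3.27. The 12 heavy-strand mRNAs ran from -0.28 (MT-ND3) to 1.91 (MT-ND5). The 2 clones differed in ANKFY1, a gene of endosome traffic, at 12.0 to 15.5 on the log2 scale in the clone 1 libraries and 10.1 to 11.2 in those of clone 7.

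The 2 reporter genes that the labels name varied between libraries of a day. CDT1 lay at 15.65 (clone 1) and 12.79 (clone 7) in day 0 G1, 13.76 and 12.43 in day 0 S, 14.02 in day 0 G2, 14.04 and 12.76 in day 28 G1, 13.14 in day 28 S and 13.90 in day 28 G2. GMNN lay at 15.39 and 12.93, 13.48 and 12.75, 14.81, 13.13 and 12.58, 13.20 and 12.99 in the same order. Reads of the reporter and of the native gene cannot be told apart in these counts.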
